A study of Glycine max with 12 samples.

How the data were processed

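Root RNA of soybean (Glycine max) seedlings was measured on 12 Affymetrix arrays. Per the labels' protocols, seedlings were placed in 0.5 mM CaCl2 at pH 4.3 with 0 or 25 µM AlCl3 and roots were taken after 6, 12 and 24 h. Per the labels, 0.1 µg of total RNA was turned into biotin-labelled cDNA for each array by the standard protocol of the manufacturer. The Al-sensitive variety Guangfengmaliaodu is written GF and the Al-tolerant variety KF, as in the labels. Each of the 12 combinations of variety, treatment and time has 1 array, so there are no replicates of any condition.

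The values used are the deposited intensity values, 1 per probe set and array, on a linear scale, normalized across the arrays by the authors. Their normalization method and summarisation tool are not given in the sources used here; the scale and the normalization were read from the values, whose quartiles nearly coincide between the 12 arrays. The deposited annotation gives, per the file headers, the position, the number of probes and the gene and transcript text of each probe set, and these columns hold no measurement. A further 24 deposited columns of per-sample signals and calls carry column numbers that match no sample label and were not used here.

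The deposited values cover 75990 probe sets, of which 66195 are of the main category. The base 2 logarithm of each deposited intensity was taken with no pseudocount. Main probe sets in the lowest 0.25 of mean log2 intensity over all 12 arrays (below 1.12) were left out, which left 49646 for testing. Among the main probe sets 33493 carried 1 gene, 2040 carried several and 30662 carried none. Of those with 1 gene, 31963 had their identifier in the reference table of genes, and 1285 symbols changed by this step. The annotation marks 7523 main probe sets as able to bind transcripts of several genes, and named genes of this kind are pointed out. Coordinates are those of the array annotation, whose cells cite transcripts of assembly V1.0.

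Models were fitted with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3, with data.table version 1.17.8. For the Al effect, each variety and time formed a block of 1 control and 1 Al array, with an Al coefficient per variety (4 residual degrees of freedom) or per time (3 residual degrees of freedom). For variety differences, each treatment and time formed a block, with a variety coefficient per treatment (4 residual degrees of freedom). The time contrast of 24 h minus 6 h was fitted with blocks of variety and treatment (6 residual degrees of freedom). Since no condition was repeated, the spread behind every p-value is the variation of an effect between time points or varieties, and the spread is shared between the varieties. P-values were adjusted by the Benjamini-Hochberg method over the 49646 probe sets of a comparison, and a probe set is called when its adjusted p is below 0.05. Single pairs of arrays were described by counts of probe sets with at least a 2-fold difference, without a p-value. The number of arrays limits the precision of every value. In 1 simulated data set of 49646 probe sets, 100 were changed by 1 log2 unit and 100 others by 2, equally at every time and in both varieties. The deposited data held more calls and effects that varied with time, so the recovered shares need not carry over. For the Al effect over both varieties the test recovered 45% of changes of 1 log2 unit and 89% of changes of 2 log2 units. The corresponding shares were 23% and 74% for GF, and 22% and 72% for KF, with 7, 3 and 6 false calls in these 3 comparisons.

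The comparisons, the gene groups, the rule for naming genes and all alternatives but cyclic loess normalization were fixed before the data were examined. Gene groups were 44 lists of gene families found by expressions on the annotation text. They cover peroxidases and other redox enzymes, transporters, cell wall enzymes, hormone genes, transcription factor families, growth-related genes, and markers of shoot, cotyledon, nodule, endodermis and root hair. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and comparisons of a family, and again with an estimated correlation and with fry. List means relative to all probe sets were also tested by an exact two-sided sign-flip permutation test over 6 pairs, with 64 flips and a smallest possible p of 0.0312. For single pairs, the median of a list was ranked among 10000 random lists of the same size and similar mean intensity. Numbers of list members count probe sets.

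Per comparison the rule for naming genes takes the 8 largest rises and 8 largest falls among called probe sets with an annotated gene and the same sign in every pair. Where fewer than 4 passed in a direction, it takes the 4 largest changes of at least 2-fold in every pair, which are described as not passing. It adds up to 4 members of each list by absolute change, the 5 largest rises and falls of class III peroxidases per variety, and each Al tolerance factor and malate or citrate transporter that passed in a variety. For a gene with several probe sets, the one with the highest mean intensity is named.

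Alternatives to the filter, the normalization, the eBayes trend, the blocks, the fold threshold, the list test and the choice of arrays were run, and leave-one-out fits dropped each pair and each time point in turn. Cyclic loess normalization was added after the data were seen. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.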

Results

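Genome-wide root expression was measured in an Al-sensitive soybean variety, GF, and an Al-tolerant one, KF, after 6, 12 and 24 h in an acid calcium solution with or without 25 µM AlCl3. Aluminium ions in acid solution stop root growth, and the series was made to find candidate genes for tolerance, with peroxidases in its title. There were 12 arrays, 1 for each variety, treatment and time, and 49646 probe sets were tested. No condition was replicated. Each p-value therefore measures an effect against its variation between time points, or between varieties and treatments where times are compared. Effects are log2 ratios, with the standard error of limma after the sign ±, and n is the number of pairs of arrays.

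The arrays had nearly equal medians, from 1.67 to 1.70 on the log2 scale. Background probes, which match no genome, had medians from 1.59 to 2.22, the highest in the GF 24 h control array. In that array 2479 main probe sets lay above the 95th percentile of the background probes, against 4592 to 8185 in the other arrays. The KF 24 h Al array stood furthest from the rest, with a correlation across probe sets of 0.942 with the GF 24 h Al array and of 0.78 with the GF 6 h control array. Probe sets are not independent replicates, so these correlations describe the arrays only. Chloroplast probe sets were lower with Al in 6 of 6 pairs, by −0.94 in GF and −0.73 in KF at 24 h (exact two-sided sign-flip p = 0.0312, the smallest possible). Positive control probe sets were also lower in 6 of 6 pairs, with a mean of −0.59 (SD 0.28, n = 6; exact p = 0.0312), and intron probe sets in 6 of 6 as well, with a mean of −0.24 (SD 0.086, n = 6; exact p = 0.0312). The rRNA probe sets differed by −0.05 on average (lower in 4 of 6; exact p = 0.312). Where a gene lies near background in a group of arrays, the size of its log2 ratio and the standard error depend on that background.

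How far expression moved with Al was first counted within each pair of arrays. In GF, 2628 probe sets differed at least 2-fold between the Al and control array at 6 h, 3688 at 12 h and 7083 at 24 h. In KF the counts were 3003, 5767 and 12568, ratios of KF over GF of 1.14 at 6 h, 1.56 at 12 h and 1.77 at 24 h. At 1.5-fold the order at 6 h was the reverse, with 8213 in GF and 7966 in KF. At 24 h in KF, 5594 probe sets were higher and 6974 lower with Al; after cyclic loess normalization the balance turned, with 6837 higher and 4785 lower. The KF 12 h pair had 2853 higher and 2914 lower as deposited, and 3436 higher and 1996 lower after cyclic loess normalization. These counts have no test, since each condition has 1 array.

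**Figure D1:**
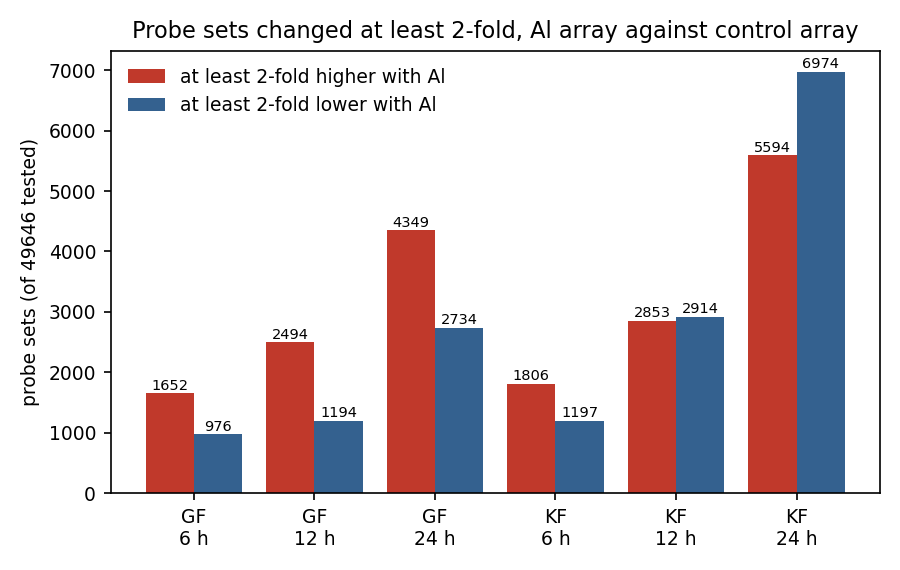
Number of probe sets, of 49646 tested, that were at least 2-fold higher (red bars) or lower (blue bars) in the Al array than in the control array of the same variety and time, 1 pair of arrays per position. Counts are larger at 24 h than at 6 h in both varieties, and the KF 24 h pair has the largest, 5594 higher and 6974 lower.

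The first test was of the Al effect averaged over both varieties. Al raised a group of genes from near background to high signal in every pair, so the sizes of these rises depend on the background. LOC100793725 (GLYMA03G35930, chromosome 3, 42985148 to 42986060), a putative syntaxin-24-like gene of the family of membrane fusion proteins, rose by 7.16 ± 0.27 (n = 6, adjusted p = 0.00024). The stress-related zinc finger gene LOC100781211, ZAT11-like (GLYMA13G40860, chromosome 13, 41313666 to 41314265), rose by 6.52 ± 0.36 (adjusted p = 0.000332). WRKY30, a transcription factor (GLYMA17G33891, chromosome 17, 37802115 to 37803840), rose by 5.73 ± 0.28 (adjusted p = 0.000259). Further rises were those of the transcription factor gene LOC778082 (MYB67, 6.47), the nudix hydrolase 2-like gene LOC100801176 (6.21), the calcium-binding PBP1-like gene LOC100775872 (5.91), the resistance protein gene LOC547561 (LM12, 5.81) and the coatomer beta-2-like gene LOC100807969 (5.75). The deepest falls included an enzyme of the last step to active gibberellin. LOC100817159, gibberellin 3-beta-dioxygenase 3-like (GLYMA04G07480, chromosome 4, 5832199 to 5834434), fell by 3.76 (± 0.27, adjusted p = 0.000767), and LOC100816056, peroxidase 4-like (GLYMA18G06220, chromosome 18, 4808002 to 4811827), fell by 3.49 (± 0.35, adjusted p = 0.00252). Other falls were those of the UDP-glycosyltransferase 74E2-like gene LOC100805695 (−2.72), the branched-chain aminotransferase gene LOC100778723 (−2.68), the nitrite transporter gene LOC100786998 (−2.66), the subtilisin-like protease gene LOC100808547 (−2.47), the alpha-xylosidase-like gene LOC100808526 (−2.44) and the polygalacturonase gene LOC732602 (−2.38). Each gene named here kept its direction in 6 of 6 pairs, which the rule for naming genes required.

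In total 6841 probe sets were called for Al over both varieties, 3270 higher and 3571 lower, and 1998 of the higher and 1221 of the lower ones by at least 2-fold. The balance turned after cyclic loess normalization, with 3854 higher and 2862 lower, and with no blocks, with 3515 higher and 2945 lower. It turned as well in each leave-one-out fit except that without the KF 6 h pair, for example to 2813 higher and 2503 lower without the KF 24 h pair. The count was 2666 without the GF 6 h pair, 2057 without the GF 12 h pair, 2502 without the GF 24 h pair, 1908 without the KF 12 h pair, 2715 without the 6 h arrays and 93 without the 12 h arrays. An additive time effect in place of blocks gave 10604.

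Among gene groups, the WRKY, NAC and ERF families of transcription factors were called as higher. Of 119 WRKY probe sets 41 rose, 1 fell and 77 did not pass (57 and 4 adjusted over the list alone), with a mean of 1.16 (camera adjusted p = 2.34e-16; adjusted p = 0.518 with an estimated correlation). Examples are a pair of WRKY40-like genes, LOC100798500 (5.35, on a probe set able to bind several genes) and LOC100810978 (4.91). Of 85 NAC probe sets 32 rose, 1 fell and 52 did not pass (39 and 2 adjusted over the list alone), with a mean of 1.07 (camera adjusted p = 1.86e-14; adjusted p = 0.518 with an estimated correlation). This list was led by NAC8-like LOC100791680 (4.91) and NAC6 (4.27). In the ERF family, which includes ethylene-responsive factors, 27 of 170 rose and 8 fell (34 and 12 adjusted over the list alone; mean 0.30, camera adjusted p = 0.000469; adjusted p = 0.537 with an estimated correlation), with AP2-5 at 3.53.

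Some hormone and signalling lists were higher and others were not called. Auxin (camera adjusted p = 0.64), abscisic acid (0.826), gibberellin (0.536) and cytokinin genes (0.11) were not called. For jasmonate genes 20 of 84 rose and 2 fell (21 and 4 adjusted over the list alone; mean 0.61, camera adjusted p = 6.96e-05; adjusted p = 0.518 with an estimated correlation). The jasmonate repressor genes LOC100803886 (TIFY 5A-like, 5.21) and LOC100815478 (TIFY 10A-like, 4.23) and the lipoxygenase gene LOC100795276 (3.60) led this list. Ethylene synthesis had 12 rises and 6 falls among 53 (15 and 6 adjusted over the list alone; mean 0.37, camera adjusted p = 0.0277; adjusted p = 0.518 with an estimated correlation). It was led by the oxidase gene LOC100783009 (3.14) and the synthase gene LOC100797692 (2.98). Calcium signalling had 24 rises and 5 falls among 125 (31 and 6 adjusted over the list alone; mean 0.34, camera adjusted p = 1.5e-05; adjusted p = 0.518 with an estimated correlation), with the calmodulin-binding kinase gene LOC100305423 at 1.91. Of 48 glutathione S-transferase probe sets, detoxification enzymes, 15 rose and 3 fell (18 and 5 adjusted over the list alone; mean 0.55, camera adjusted p = 0.000225; adjusted p = 0.518 with an estimated correlation), led by GSTU42 (4.90) and LOC547581 (3.69). Phosphate starvation genes had 12 rises and 4 falls among 63 (22 and 6 adjusted over the list alone; mean 0.35, camera adjusted p = 0.0155; adjusted p = 0.518 with an estimated correlation). Their largest rise was that of the purple acid phosphatase 20-like gene LOC100794764 (4.70).

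Lists of protein synthesis, DNA replication, cell division and the cytoskeleton were lower. Of 269 cytosolic ribosomal protein probe sets 142 fell, 1 rose and 126 did not pass (210 and 2 adjusted over the list alone), with a mean of −0.70 (camera adjusted p = 6.85e-27; adjusted p = 0.518 with an estimated correlation). The ribosomal protein L3-like gene LOC100792174 fell by 2.23, and the single riser was the L10-like gene LOC100779884 (2.31). Of 85 probe sets for histones and DNA replication 53 fell and 0 rose (59 and 0 adjusted over the list alone; mean −0.79, camera adjusted p = 4.85e-14; adjusted p = 0.518 with an estimated correlation). Among them were the replication licensing gene LOC100791302 (MCM3, −2.05) and the proliferating cell nuclear antigen gene LOC100817651 (−1.84). Cyclins and mitosis had 56 falls and 3 rises among 164 (72 and 5 adjusted over the list alone; mean −0.48, camera adjusted p = 1.33e-07; adjusted p = 0.518 with an estimated correlation). The mitotic cyclin CYCB1;1 was at −2.03, and the cyclin-D1-1-like gene LOC100781193 rose by 3.19. For tubulins and actins, the cytoskeleton, 18 of 62 fell and 0 rose (36 and 0 adjusted over the list alone; mean −0.63, camera adjusted p = 2.29e-09; adjusted p = 0.537 with an estimated correlation), with tubulin beta-1-like LOC100819408 at −1.69. In each of the 6 pairs the median of the ribosomal, the histone and the cyclin list lay at percentile 0 of 10000 random lists. The positive control, chloroplast and intron probe sets described above were lower in the same 6 pairs.

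**Figure D2:**
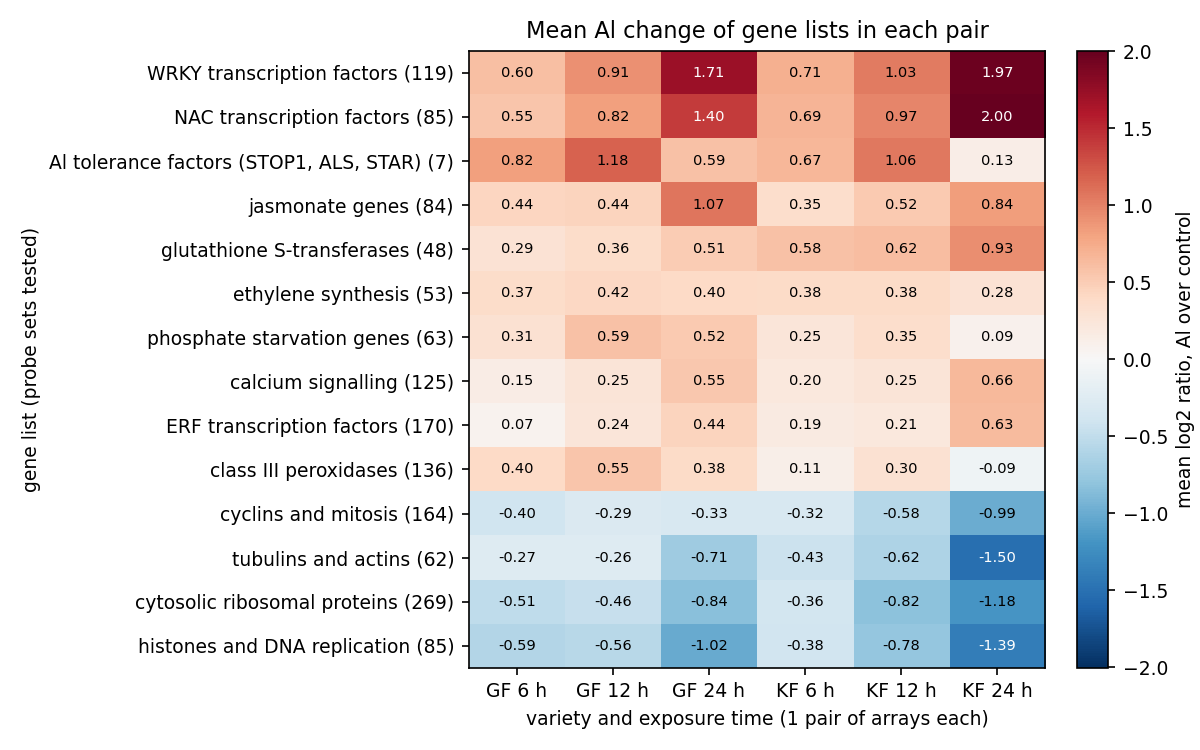
Mean log2 ratio of Al over control for the 14 gene lists called over both varieties (rows, with the number of probe sets tested), in each of the 6 pairs of arrays (columns); red is higher and blue lower with Al. WRKY means range from 0.60 to 1.97 and ribosomal protein means from −1.18 to −0.36, and the peroxidase mean is −0.09 in the KF 24 h pair and above 0 in the other pairs.

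Cell wall lists were mixed and not called. Among 43 xyloglucan endotransglucosylase probe sets, which loosen or rejoin wall polymers, 8 rose and 6 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.213), with LOC100807063 (5.70) and LOC100800547 (4.97) as the largest rises. Pectin enzymes had 12 rises and 19 falls among 196 (14 and 20 adjusted over the list alone; camera adjusted p = 0.709), with the pectinesterase gene LOC100800971 at 3.75. For lignin and phenylpropanoid synthesis 12 of 92 rose and 5 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.326), including PAL1.2, the entry enzyme of the pathway, at 2.86. Among marker lists of other tissues, 0 of 47 photosynthesis probe sets rose and 1 fell (mean −0.14), 2 of 46 seed storage probe sets rose and 1 fell, and 0 of 20 nodule and 0 of 4 root hair probe sets passed. Among 48 endodermis probe sets 6 rose and 1 fell (camera adjusted p = 0.293). For endodermis, cytochrome P450, flavonoid, gibberellin, heat shock, circadian, abscisic acid and ROS scavenger lists the mean was above 0 and the median below 0, and none of these lists was called. For auxin, nodule, seed storage and nitrate lists the mean was below 0 while the direction of camera was up, and none of these was called either. With fry 0 of 44 lists were called, and 19 lists reached the smallest exact two-sided sign-flip p of 0.0312 over 6 pairs, with an adjusted p of 0.0724, so none passed. The peroxidase list had an exact p of 0.0625.

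The Al-sensitive variety was tested next. Its effect comes from its own 3 pairs, and the spread is shared with KF in a fit of all 12 arrays. In GF the largest rises were those of the syntaxin gene LOC100793725 (7.06 ± 0.38, n = 3, adjusted p = 0.00345) and of LOC100792203. The latter (GLYMA13G27300, chromosome 13, 30471532 to 30477485) is a MATE efflux gene like FRD3, whose family includes citrate exporters (6.31 ± 0.39, adjusted p = 0.0039). The xyloglucan endotransglucosylase gene LOC100807063 rose by 5.63 and WRKY30 by 5.46. The largest fall was that of the miraculin-like gene LOC100790688 (−3.10 ± 0.28, adjusted p = 0.00834), followed by the gibberellin enzyme LOC100817159 (−2.89) and LOC100805695 (−2.61). A pair of auxin-binding ABP19a-like genes, LOC100809937 (−2.39) and LOC100813853 (−2.08), and the alcohol dehydrogenase-like gene LOC100783318 (−2.27) also fell. In all, 411 probe sets were called in GF, 357 higher and 54 lower. The WRKY list had 11 rises among 119 (31 adjusted over the list alone; mean 1.07, camera adjusted p = 2.21e-16; adjusted p = 0.518 with an estimated correlation). Of 269 ribosomal probe sets 0 passed (0 adjusted over the list alone), although the list mean was −0.60 (camera adjusted p = 6.85e-27; adjusted p = 0.518 with an estimated correlation). The number of calls in GF was 102 without the GF 6 h pair, 5 without the GF 12 h pair, 42 without the GF 24 h pair, and 175 without the KF 12 h pair. It was 26 without the 6 h arrays and 0 without the 12 h arrays (3860 at an unadjusted p below 0.05, limma). It was 1423 without the KF 24 h pair and 1266 without the 24 h arrays. It was 794 with no blocks and 1352 with an additive time effect.

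In the tolerant variety KF the same syntaxin gene LOC100793725 rose by 7.26 ± 0.38 (n = 3, adjusted p = 0.00123), MYB67 (LOC778082) by 6.88 and ZAT11-like LOC100781211 by 6.86. The largest falls were those of a pair of peroxidase genes, of the gibberellin enzyme LOC100817159 (−4.64 ± 0.39, adjusted p = 0.003) and of the aminotransferase gene LOC100778723 (−4.03). Other falls were those of the xyloglucan endotransglucosylase 32-like gene LOC100781528 (−3.47) and the alpha-L-arabinofuranosidase gene LOC100787734 (−3.11). The lists of xyloglucan endotransglucosylases (6 of 43 rose and 4 fell, 10 and 9 adjusted over the list alone; camera adjusted p = 0.261) and of pectin enzymes (4 of 196 rose and 7 fell, 4 and 9 adjusted over the list alone; camera adjusted p = 0.847) were not called in KF. In KF 2719 probe sets were called, 1381 higher and 1338 lower. The split was 1635 and 1084 after cyclic loess normalization, 1667 and 938 with no blocks, 2812 and 3809 with an additive time effect, and 1533 and 1648 with 33097 brighter probe sets tested. Ribosomal proteins had 40 falls and 1 rise among 269 (168 and 1 adjusted over the list alone; mean −0.79, camera adjusted p = 1.07e-23; adjusted p = 0.518 with an estimated correlation). Glutathione S-transferases had 12 rises and 2 falls among 48 (16 and 3 adjusted over the list alone; mean 0.71, camera adjusted p = 8.58e-05; adjusted p = 0.518 with an estimated correlation). The number of calls in KF was 1317 without the GF 6 h pair, 965 without the GF 12 h pair, 254 without the KF 12 h pair and 917 without the KF 24 h pair. It was 794 without the 6 h arrays and 0 without the 12 h arrays (6912 at an unadjusted p below 0.05, limma). The count was 403 when the 6 KF arrays were fitted alone and 6621 with an additive time effect. The order of the counts of GF and KF turned without the KF 24 h pair (1423 and 917) and when each variety was fitted alone (438 and 403). It did not turn without all 24 h arrays (1266 and 3293). Without the KF 24 h pair, KF has fewer pairs than GF and the shared spread changes. That turn therefore does not compare the size of the responses.

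The calls of both varieties overlapped. Of the 411 probe sets called in GF, 346 were also called in KF, all in the same direction. Both effects come from a single fit with a shared spread, which favours calls in both, so no chance expectation is given for this number. A further comparison of signs gave 405 of the 411 GF calls and 2649 of the 2719 KF calls with the same sign of the mean change in the other variety. Across probe sets the mean Al effects of GF and KF had a Pearson r of 0.849 and a Spearman rho of 0.684. At matched times r was 0.58 at 6 h, 0.732 at 12 h and 0.804 at 24 h.

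Class III peroxidases, secreted enzymes that use hydrogen peroxide and cross-link wall phenolics, are the genes in the title of the series. Members moved in both directions. Over both varieties 28 of 136 probe sets rose, 7 fell and 101 did not pass (33 and 11 adjusted over the list alone), with a mean of 0.28 (camera adjusted p = 0.00533; adjusted p = 0.518 with an estimated correlation). Without the 12 h arrays the mean was 0.20 and the call was lost (adjusted p = 0.055). LOC100782549, peroxidase 53-like, rose by 5.38 ± 0.33 in GF and 5.23 ± 0.33 in KF (adjusted p = 0.0039 and 0.00123). LOC100803637, peroxidase 52-like, rose by 3.69 in GF and 5.08 in KF, LOC100799894, cationic peroxidase 1-like, by 3.36 and 3.91 (on a probe set able to bind several genes), and LOC100805838, peroxidase 54-like, by 3.19 and 3.16. LOC100790279, also peroxidase 52-like, was at 3.05 in GF, short of the test (adjusted p = 0.177), and rose by 4.72 in KF (adjusted p = 0.03). In KF, LOC100816056, peroxidase 4-like, fell by 4.77 (± 0.50, adjusted p = 0.005), and its value in GF was −2.21 (adjusted p = 0.108). LOC100811432, cationic peroxidase 1-like (GLYMA03G04880, chromosome 3, 5075225 to 5078280), fell by 3.66 in KF (adjusted p = 0.018), with −0.41 in GF, and LOC100811277, peroxidase 21-like, fell by 2.77 (adjusted p = 0.00489), with −0.19 in GF. For none of these genes did the difference between varieties pass (adjusted p = 0.953, 0.953 and 0.561 for the 3 falls). In GF 9 of 136 rose and 0 fell (20 and 1 adjusted over the list alone; mean 0.45, camera adjusted p = 4.86e-05; adjusted p = 0.518 with an estimated correlation). In KF 13 rose and 6 fell (18 and 12 adjusted over the list alone; mean 0.11, camera adjusted p = 0.118), and the mean was 0.01 without the 12 h arrays and 0.21 without the 24 h arrays.

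The list as a whole was lower in the KF response than in the GF response by −0.34 (camera adjusted p = 0.0418; adjusted p = 0.52 with an estimated correlation). This call was lost without the filter (−0.25, adjusted p = 0.173) and without the 6 h arrays (−0.36, adjusted p = 0.311), and 0 of 136 members passed for the difference (0 higher and 1 lower adjusted over the list alone). Under Al, 11 peroxidase probe sets were lower in KF than in GF and 0 higher (23 and 4 adjusted over the list alone), with a mean of −0.40 (camera adjusted p = 0.00148; adjusted p = 0.656 with an estimated correlation). In control arrays 1 was lower and 0 higher (1 and 0 adjusted over the list alone; mean −0.06, camera adjusted p = 0.156).

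**Figure D3:**
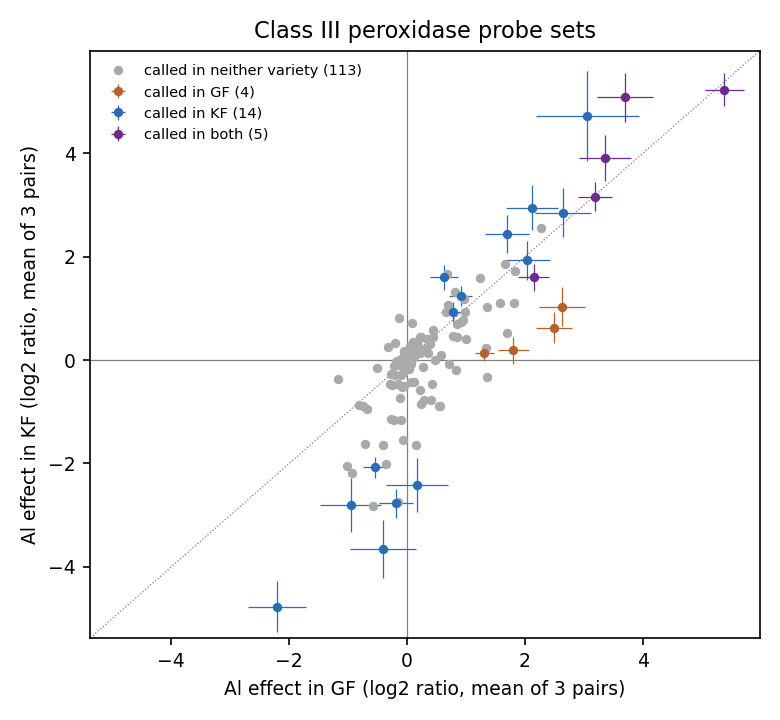
Al effect of 136 class III peroxidase probe sets in GF (horizontal axis) and KF (vertical axis), as the mean log2 ratio of 3 pairs of arrays. Bars are the limma standard error of probe sets called in at least 1 variety and the dotted line marks equal effects; 5 are called in both varieties, 4 in GF alone and 14 in KF alone, and the deepest value is −4.77 in KF.

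Among genes with known roles in Al exclusion, the list of tolerance factors was called as higher by camera and that of transporters was not. The FRD3-like efflux gene LOC100792203 rose in both varieties, from a control level of 1.72 to 8.03 in GF and from 3.33 to 8.12 in KF on the log2 scale (GF 6.31, KF 4.79 with adjusted p = 0.00285; difference not passed, adjusted p = 0.953). STOP1 is a zinc finger factor for genes of acid and Al tolerance. Among 7 Al tolerance factor probe sets 3 rose and 0 fell over both varieties (4 and 0 adjusted over the list alone; mean 0.74, camera adjusted p = 0.00483; adjusted p = 0.518 with an estimated correlation). These were the STOP1-like genes LOC100804910 (1.52) and LOC100801536 (0.999) and the ALS3-like gene LOC100802735 (1.26), whose family moves Al within the plant. Among 61 malate and citrate transporter probe sets 3 rose and 5 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.881). The list mean was 0.01, which turned to −0.01 after median centring, and the median was −0.04. The median level of these probe sets was 1.59 on the log2 scale, against 4.64 for the tolerance factors. Background probes had medians from 1.59 to 2.22, so many transporter probe sets could hardly show a change. The lists are therefore not compared on equal terms. In KF the ALMT12-like gene LOC100809994 (−1.503), ALMT16 (−1.11) and the MATE genes LOC100813142 (−1.34), LOC100801964 (−1.14) and LOC100816717 (−1.08) fell and the MATE gene LOC100800053 rose (1.498). For none of these genes did the difference between the varieties pass, so these changes are not shown to be particular to KF.

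Whether the varieties responded differently was tested directly as the Al effect in KF minus that in GF. A pair of genes passed, in opposite directions, and both were near background in 1 variety. LOC100809397, GDSL esterase/lipase 5-like (GLYMA15G41850, chromosome 15, 49063505 to 49067864), a family of lipid-cleaving enzymes, rose by 4.73 in KF and was at 0.07 in GF, a difference of 4.66 ± 0.19 (adjusted p = 0.00126). Its signal in GF and in KF control arrays lay below the median of the background probes, so this size is not an exact fold. SYP24, putative syntaxin-24-like (GLYMA19G38570, chromosome 19, 45459111 to 45459981), rose by 5.39 in GF and was at 0.24 in KF, a difference of −5.15 ± 0.37 (adjusted p = 0.0427). Its signal in KF and in GF control arrays was near background, so this size is not an exact fold either. LOC100793725, the other gene annotated as syntaxin-24-like, rose in both. The mean level of LOC100809397 was 5.49 in KF with Al, and single arrays of the other 3 groups lay from 0.696 to 1.055. The mean level of SYP24 was 7.70 in GF with Al and 1.64 in KF with Al.

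Of the 49646 probe sets these 2 were called for the difference. At an unadjusted p below 0.05 (limma) there were 2200, fewer than the share of 0.05 that no difference at all would give. Among alternatives with the same 49646 probe sets this count ran from 1145 without the 12 h arrays to 3286 without the KF 6 h pair. The test does not match the varieties on time, so changes of the Al effect with time that both share add to its spread. Few calls therefore do not show that the varieties respond alike. Genes with large differences that did not pass include LOC100782055, glutelin type-A 1-like (4.77, adjusted p = 0.0643), and GSTU24, a glutathione S-transferase (4.52, adjusted p = 0.0573), both on probe sets able to bind several genes, and the expansin-like gene LOC100778424 (4.08, adjusted p = 0.457). GSTU24 passed with no filter (adjusted p = 0.0392), 1 probe set per gene (0.0444), no blocks (0.00218) and additive time (0.00805), and without the KF 24 h pair (0.0216) or the 24 h arrays (0.0253). LOC100782055 passed with 1 probe set per gene (0.0476), additive time (0.0484), and without the KF 24 h pair (0.0285) or the 24 h arrays (0.0253), and LOC100778424 without the 24 h arrays (0.0253). On the other side, WRKY72-like LOC100809801 (−3.39, adjusted p = 0.953), the gibberellin enzyme GA3OX3 (−2.66, adjusted p = 0.953) and the Nod factor receptor gene NFR5A (−2.64, adjusted p = 0.517) did not pass. The WRKY72-like LOC100809801 value was −2.25 without the KF 12 h pair and −2.001 without the 12 h arrays, and the GA3OX3 value was −1.64 without the KF 24 h pair. The SYP24 call was lost with cyclic loess normalization (adjusted p = 0.0518), without the eBayes trend (adjusted p = 0.0993). It was also lost (adjusted p in brackets) without the GF 6 h (0.125), GF 12 h (0.352), GF 24 h (0.0589), KF 6 h (0.158) or KF 12 h pair (0.403), the 6 h arrays (0.72) or the 12 h arrays (1). LOC100809397 lost its call without the GF 12 h pair (adjusted p = 0.0614), the 6 h arrays (0.316) or the 12 h arrays (0.437).

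As groups, tubulins and actins (−0.44, camera adjusted p = 5.41e-05; adjusted p = 0.72 with an estimated correlation) were lower in the KF response. So were cyclins and mitosis (−0.29, camera adjusted p = 0.000142; adjusted p = 0.636 with an estimated correlation), with 0 of 62 and 0 of 164 members passing (0 and 0 adjusted over the list alone). Aquaporins, water channels, were lower as well (−0.54, camera adjusted p = 0.000808; adjusted p = 0.537 with an estimated correlation; 0 of 38 passing and 0 adjusted over the list alone). Glutathione S-transferases were higher (0.32, camera adjusted p = 0.00303; adjusted p = 0.518 with an estimated correlation; 0 of 48 passing, 1 higher adjusted over the list alone). In total 10 lists were called, 4 higher and 6 lower, and 6 without the 24 h arrays. The aquaporin means in KF and GF were −0.373 and 0.004 at 6 h, −0.157 and 0.187 at 12 h, and −1.049 and −0.148 at 24 h. At 24 h, where the KF Al array stood apart, positive control probe sets were at −1.056 in KF and −0.711 in GF. An exact two-sided permutation of 3 against 3 pairs, not matched on time, cannot go below p = 0.1. It gave 0.5 for tubulins and actins, 0.3 for cyclins, 0.2 for aquaporins and 0.1 for glutathione S-transferases. At 6 h the cyclin means went the other way, with −0.32 in KF and −0.40 in GF.

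The course in time was tested as the Al effect at 24 h minus that at 6 h. The largest gains by 24 h included genes annotated for disease resistance, and the largest losses included several cell wall genes. The list of defence proteins was not called, with 8 of 181 higher and 0 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.995). Pectin enzymes (camera adjusted p = 0.0714), expansins (0.0653) and cyclins (0.0636) were not called either. LOC100799496, a probable F-box gene (GLYMA09G00720, chromosome 9, 389910 to 391184), gained 6.72 ± 0.33 (n = 2 varieties, adjusted p = 0.00169), and the elicitor-responsive gene LOC100802187 gained 6.24 ± 0.26 (adjusted p = 0.000823). The disease resistance genes LOC100808032 (6.99) and LOC100802182 (5.91), the F-box genes LOC100796982 (6.51) and LOC100796453 (5.77), the lignin-forming peroxidase gene LOC100786161 (6.43) and the glutamate decarboxylase gene LOC100812201 (5.56) gained as well. Losses were those of the CASP-like gene LOC100500346 (−3.70), of a family of Casparian strip proteins, the cellulose synthase gene LOC100814262 (CESA3-like, −3.41), the arabinogalactan gene LOC100808347 (−3.36), the MAGPIE-like gene LOC100778666 (−3.08) and the pectinesterase gene LOC100813592 (−3.03). The 5NG4-like gene LOC100783910 (−3.58) and the actin-depolymerizing gene LOC100793035 (−2.78) also lost, both on probe sets able to bind several genes, as did the nitrite transporter gene LOC100787538 (−2.62).

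Here 1053 probe sets were called, 968 higher and 85 lower. The control categories moved between these times too: the Al difference of positive control probe sets was −0.46 at 6 h and −0.71 at 24 h in GF, and −0.31 and −1.06 in KF. That of chloroplast probe sets was −0.15 and −0.94 in GF, and −0.07 and −0.73 in KF. The contrast also uses the KF 24 h Al array, which stood apart. The WRKY list gained 1.18 on average, with 20 of 119 higher and 0 lower (49 and 0 adjusted over the list alone; camera adjusted p = 1.84e-17; adjusted p = 0.518 with an estimated correlation). The NAC list gained 1.08, with 15 of 85 higher (34 and 1 adjusted over the list alone; camera adjusted p = 2.52e-10; adjusted p = 0.518 with an estimated correlation). Histones and DNA replication had a mean of −0.72 with 6 of 85 lower (17 adjusted over the list alone; camera adjusted p = 2.29e-09; adjusted p = 0.518 with an estimated correlation). Cellulose synthases had a mean of −0.66 with 1 of 37 lower (1 adjusted over the list alone; camera adjusted p = 0.000617; adjusted p = 0.518 with an estimated correlation). The call count was 0 without the GF 6 h pair (4781 at an unadjusted p below 0.05, limma), 78 without the KF 6 h pair, 485 without the GF 12 h pair, 472 without the KF 12 h pair, and 469 without the 12 h arrays. Without a 6 h or 24 h pair, 1 of the compared times rests on a single pair of arrays. Such a fit tests that pair against the spread of the other times. Its count therefore does not describe the same comparison, and none is given without a 24 h pair. With an additive time effect the call count was 1916.

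Differences between the varieties averaged over both treatments were tested over 6 pairs matched on treatment and time. Several were close to presence against absence of signal. LOC100803799, ruBisCO-associated protein-like (GLYMA03G02870, chromosome 3, 2696108 to 2696799), was lower in KF by −6.73 ± 0.32 (n = 6, adjusted p = 1.4e-05). Its level ran from 5.44 to 8.52 in GF control arrays and had a mean of 9.67 in GF Al arrays. In KF the mean levels were 1.62 in control and 1.65 in Al arrays. The KF levels are about the median of the background probes, and those of LOC100785561 in GF are below it, so these sizes are not exact folds. The receptor-like kinase gene LOC100785561 (GLYMA09G35011, chromosome 9, 41254527 to 41258109) was higher in KF by 4.37 ± 0.21 (adjusted p = 1.5e-05), and the F-box gene LOC100820469 by 3.92 ± 0.18 (adjusted p = 1.4e-05). Also higher in KF were the LURP-one-like gene LOC100781192 (3.55), the ubiquitin ligase gene LOC100797586 (3.30), the resistance gene LOC100305359 (3.14), IMT1, a methyltransferase gene like those of lignin synthesis (2.96), and the resistance gene LOC100817360 (2.86). Lower in KF were the peroxidase gene LOC100811432 (−3.52), the annexin D4-like gene LOC100784954 (−3.38), the miraculin-like gene LOC100790688 (−3.35), the ANXUR2-like kinase gene LOC100787367 (−3.32), the trypsin inhibitor gene LOC100811209 (−3.17) and the RPM1-like resistance gene LOC100784168 (−3.11). For SYP24 (−3.48) and LOC100782055 (3.02, on a probe set able to bind several genes) the average came mostly from the Al arrays, with control levels of 2.31 and 2.18 in GF and 1.40 and 2.81 in KF.

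**Figure D4:**
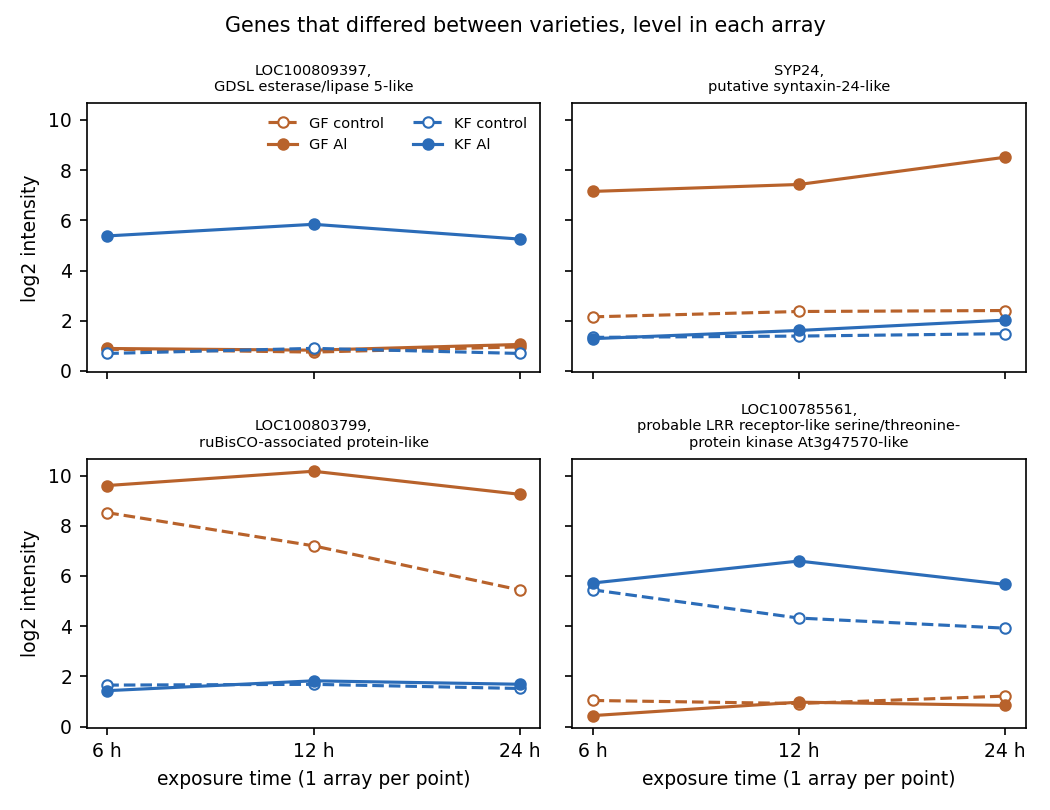
Log2 intensity of 4 genes in each of the 12 arrays, by exposure time; brown is GF, blue is KF, open points with dashed lines are control arrays and filled points with solid lines are Al arrays. LOC100809397 is high in KF with Al alone and SYP24 in GF with Al alone, while LOC100803799 and LOC100785561 differ between the varieties in both treatments.

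Over both treatments 1879 probe sets were called, 1076 higher and 803 lower in KF. The call count was 1067 without the control 6 h pair, 699 without the control 12 h pair, 887 without the control 24 h pair, and 1144 without the Al 12 h pair. It was 563 without the 6 h arrays and 298 without the 12 h arrays, and 1105 with 1 probe set per gene, 746 with no blocks and 1055 with an additive time effect. Heat shock proteins were higher in KF, with 8 of 118 higher and 0 lower (20 and 0 adjusted over the list alone; mean 0.19, camera adjusted p = 0.00123; adjusted p = 0.656 with an estimated correlation), among them HSP90A1 (0.93). Abscisic acid and dehydration genes were lower, with 4 of 50 (4 adjusted over the list alone; mean −0.15, camera adjusted p = 0.00436; adjusted p = 0.656 with an estimated correlation), among them the receptor gene LOC100808416 (−1.08). Class III peroxidases had 10 of 136 lower and 0 higher (16 and 1 adjusted over the list alone; mean −0.23, camera adjusted p = 0.00374; adjusted p = 0.656 with an estimated correlation), with RIP1, peroxidase 4-like, at −2.51 and LOC100811277 at −2.12.

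In control arrays alone 626 probe sets differed between the varieties, 410 higher and 216 lower in KF. The resistance gene LOC100305359 was higher by 4.09 ± 0.46 (n = 3, adjusted p = 0.00405) and LOC100798933, an RPM1-like resistance gene, by 3.40. The transcription factor gene LOC100778242 (KAN4-like) was higher by 3.13. Lower in KF were LOC100803799 (−5.44), LOC100790688 (−4.68), the trypsin inhibitor gene LOC100811209 (−4.34), and the metalloproteinase gene SLTI114 (−3.83). So were the pyruvate decarboxylase gene LOC100808751 (−3.52, on a probe set able to bind several genes), the potassium channel subunit gene LOC100781297 (−3.48), the expansin-like gene LOC100778424 (−3.47) and the amino acid transporter gene LOC100800330 (−3.02). The call count was 219 without the control 6 h pair, 124 without the control 12 h pair, 219 without the control 24 h pair, 1254 without the Al 24 h pair, 108 without the 6 h arrays and 75 without the 12 h arrays. It was 279 with 1 probe set per gene and 269 with no blocks, and 409 with an additive time effect.

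Under Al 1119 probe sets differed, 614 higher and 505 lower in KF. LOC100803799 was lower by −8.03 ± 0.45 (n = 3, adjusted p = 8.56e-05), and the cationic peroxidase gene LOC100811432 (−5.15) and RIP1 (−3.80) were lower too. LOC100782055 (5.402), LOC100785561 (5.24), LOC100809397 (4.56), GSTU24 (4.55) and the glycolipid transfer gene LOC100813626 (4.09) were higher. Aquaporins had 3 of 38 lower and 0 higher (9 and 0 adjusted over the list alone; mean −0.48, camera adjusted p = 0.0007; adjusted p = 0.656 with an estimated correlation). Glutathione S-transferases had 4 of 48 higher and 0 lower (6 and 0 adjusted over the list alone; mean 0.33, camera adjusted p = 0.0266; adjusted p = 0.656 with an estimated correlation), the single list that fry also called (adjusted p = 0.0227). The call count was 665 without the control 6 h pair, 519 without the control 12 h pair, 736 without the control 24 h pair, 658 without the Al 6 h pair, 503 without the Al 12 h pair, 279 without the 6 h arrays and 126 without the 12 h arrays. It was 705 with 1 probe set per gene, 296 with no blocks and 399 with an additive time effect.

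Time in solution over both treatments, 24 h minus 6 h, was compared last, on 4 pairs. There were 2 calls, 0 higher and 2 lower at 24 h, against 16004 probe sets at an unadjusted p below 0.05 (limma). The fit takes 1 time effect over control and Al arrays, so changes of the Al effect with time add to its spread. Few calls therefore do not show that expression stayed the same. Time in solution cannot be told apart from time of day. The background median also rose, from 1.63 at 6 h to 1.92 at 24 h. The call count was 235 after quantile normalization (168 higher and 67 lower), 377 after median centring (254 higher and 123 lower), 494 after cyclic loess normalization (331 higher and 163 lower), 807 with 33097 brighter probe sets tested (264 higher and 543 lower) and 1078 without the eBayes trend (348 higher and 730 lower). It was 0 without the filter (17938 at an unadjusted p below 0.05, limma).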

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

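The poly-A spike comparison and the comparison of probe sets near background in GF were chosen after the results were seen.

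Genes and groups in this part differ between varieties or between exposure times by a test of the difference itself. The Al effect of KF minus that of GF passed for 2 probe sets, LOC100809397 at 4.66 and SYP24 at −5.15. By camera with a preset correlation the lists that differed were class III peroxidases (−0.34), glutathione S-transferases (0.32), lignin and phenylpropanoid synthesis (−0.28), ERF factors (0.093), NAC factors (0.30), UDP-glycosyltransferases (0.13), aquaporins (−0.54), cyclins and mitosis (−0.29), ribosomal proteins (−0.19) and tubulins and actins (−0.44). With an estimated correlation none of these 10 lists passed (lowest adjusted p = 0.518).

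The Al effect at 24 h minus that at 6 h passed for 1053 probe sets. The named rises were LOC100808032 (6.99), LOC100799496 (6.72), LOC100796982 (6.51), LOC100786161 (6.43), LOC100802187 (6.24), LOC100802182 (5.91), LOC100796453 (5.77) and LOC100812201 (5.56). The named falls were LOC100500346 (−3.70), LOC100783910 (−3.58), LOC100814262 (−3.41), LOC100808347 (−3.36), LOC100778666 (−3.08), LOC100813592 (−3.03), LOC100793035 (−2.78) and LOC100787538 (−2.62). Lists with a larger effect at 24 h were WRKY (1.18), NAC (1.08) and ERF factors (0.41), jasmonate genes (0.56), calcium signalling (0.43), cytochrome P450s (0.34) and heat shock proteins (0.32). Lists with a lower value at 24 h were tubulins and actins (−0.76), histones and DNA replication (−0.72), cellulose synthases (−0.66) and ribosomal proteins (−0.57). None of these lists passed with an estimated correlation (lowest adjusted p = 0.518).

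Labels were exchanged within pairs, or pairs regrouped, to see how many calls other splits give. For Al over both varieties 1 of 32 splits, the real one, gave as many as 6841 calls. The highest of the others gave 2. For the variety difference over both treatments it was also 1 of 32, with 1879 calls and 17 as the highest other. This is the smallest share that 32 splits can give. Exchanging the labels of a pair moves an effect shared by all pairs into the spread, so the other splits give few calls by construction. Their low counts are therefore no further evidence, and chance is not excluded. The splits were too few for a share under 0.05 in the other comparisons. Their real counts were 411 for Al in GF, 2719 for Al in KF, 626 and 1119 for the varieties in control and under Al (4 splits each), 2 for KF minus GF (10 splits) and 2 for time (8 splits), each against 0 as the highest other.

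KF had more probe sets with at least a 2-fold Al difference than GF, by a ratio of 1.77 at 24 h. After quantile normalization the ratio was 1.61, which hardly tests a wider spread of the KF 24 h Al array left by the normalization. The quartiles of the arrays nearly coincided beforehand. The KF 24 h count went from 12568 to 12607 and that of GF from 7083 to 7818, so no conclusion is drawn. With the mean of the earlier controls in place of the 24 h controls the ratio was 1.63 (13607 and 8353 probe sets). This tests a raised background of the GF 24 h control array only in part. The GF 12 h control array had the next highest background median (1.95, against 2.22 at 24 h). In KF the controls were at 1.59 at 6 h and 1.68 at 12 h. The exchange also mixes times, so this explanation stays open. Also open is whether the KF 24 h Al array alone stands apart. The KF minus GF differences at 24 h and 12 h had a correlation across probe sets of 0.2996, just under the bound of 0.3 set for excluding this. A stronger response of the tolerant variety may also underlie the pattern, which 1 array per condition cannot tell from a deviating array.

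Ribosomal protein, histone and tubulin genes were lower with Al in 6 of 6 pairs. An intensity trend between arrays is argued against by a ribosomal mean of −0.56 after cyclic loess normalization (−0.70 as deposited), and by −0.69 for histones and −0.51 for tubulins, all below 0 in 6 of 6 pairs. The 243 of 269 ribosomal probe sets marked as unique had a mean of −0.70, so the fall was not confined to those that match several genes. Since they make up most of the list, their mean could hardly differ from that of the list, and nothing further is drawn from it. A lower mRNA content of the Al samples stays open, since the poly-A spike signals differed by −0.18 (SD 0.38, n = 6) and were higher with Al in 3 of 6 pairs. Slower growth of the root under Al may be the reason and was not measured.

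Many variety differences were present in every pair. Sequence differences between a variety and the probes stay open. Probe sets called at 2-fold had 0.979 times the mean number of probes of uncalled ones of like brightness, between the values that would have decided. For 98 of 308 probe sets lower in KF and near background in all KF arrays, the SD of the Al change in KF over that in GF was 0.275, but the 149 probe sets near background in GF gave 0.249, so the test cannot separate a lost probe match from a silent gene. Expression that truly differs between the varieties may apply as well.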

How the results depend on the processing

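Cyclic loess normalization was chosen after the data were seen; the other alternatives were planned. The planned use of a second deposited set of values was not run, since its columns match no sample label. The cause of a change was not tested unless stated.

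All 6296 values of the named genes under alternatives kept their direction, and 5201 kept their side of the threshold. The kept direction says little, since the largest changes were named only where the sign was the same in every pair. Alternatives of the filter, the eBayes trend and the blocks and the fits on 1 variety also leave the log2 ratio itself unchanged. Calls were gained in leave-one-out fits (5), with additive time (2), the brightest probe set per gene (2), no blocks (1) and no filter (1). The 1084 lost calls came from leave-one-out fits (921), no blocks (70), additive time (41), no eBayes trend (26), the fits on 1 variety (14), cyclic loess (6) and quantile normalization (4) and no filter (2). Leave-one-out fits have fewer arrays.

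With additive time the calls were 10604 for Al over both varieties, 1352 for GF, 6621 for KF, 5 for KF minus GF, 1916 for 24 h minus 6 h, and 409, 399 and 1055 for the varieties in control, under Al and over both. With no blocks they were 794 for GF, 4 for KF minus GF, and 269, 296 and 746 for the varieties. With the brightest probe set per gene, where 27839 are tested, they were 4 for KF minus GF, 279, 705 and 1105 for the varieties and 1 for time. KF minus GF had 1 call after cyclic loess and 1 without trend. KF fitted alone gave 403. Time gave 0 with no filter (17938 at an unadjusted p below 0.05, limma), 807 with 33097 brighter probe sets tested, 235 after quantile normalization, 377 after median centring, 494 after cyclic loess and 1078 without trend.

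Leave-one-out counts ran from 93 (without the 12 h arrays) to 7475 (without the KF 6 h pair) for Al over both varieties, from 0 (12 h arrays) to 1423 (KF 24 h pair) for GF, and from 0 (12 h arrays) to 3293 (24 h arrays) for KF. They ran from 0 to 6 (24 h arrays) for KF minus GF, from 0 (GF 6 h pair) to 6470 (GF 24 h pair) for 24 h minus 6 h, from 75 to 1254 for the varieties in control, 126 to 1359 under Al and 298 to 2652 over both, and from 0 to 1 for time.

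At 1.5-fold the pairs had 8213, 9738 and 13990 probe sets in GF and 7966, 12727 and 19270 in KF at 6, 12 and 24 h, so the 6 h order of the varieties turns. After cyclic loess normalization the share of higher ones rose from 49.5% to 63.3% in the KF 12 h pair (3436 higher and 1996 lower) and from 44.5% to 58.8% in the KF 24 h pair (6837 and 4785).

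With an estimated correlation 0 lists were called in every comparison, against 14, 16, 12, 10 and 11 for the Al comparisons and 5, 11 and 6 for the varieties; fry called 0, except 1 under Al. For KF minus GF 6 lists were called with no filter and 6 without the 24 h arrays. The peroxidase mean of 0.276 over both varieties had adjusted p = 0.518 with an estimated correlation and 0.0808 by fry, and without the 12 h arrays it was 0.2 (0.055). In GF 0.445 had 0.518 and 0.0948. For KF minus GF −0.338 had 0.52 and 0.204, and it was −0.252 with no filter (0.173) and −0.361 without the 6 h arrays (0.311). For 24 h minus 6 h −0.113 turned to 0.014 after cyclic loess, and this list was not called.

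Leave-one-out peroxidase means ran from 0.2 to 0.342 over both varieties, from −0.38 to −0.272 for KF minus GF, from 0.39 to 0.478 in GF and from 0.01 to 0.206 in KF. Lists that changed sign under a scaling were all among those not called. Signals near background limit small changes, with 2479 to 8185 main probe sets per array above the 95th percentile of background probes.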

Other observations

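The comparison of Bradyrhizobium and background probes was chosen after the result was seen.

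The array also carries 8250 probe sets for Bradyrhizobium, the bacterial partner of soybean nodules. For Al over both varieties 0 of them were called (890 at an unadjusted p below 0.05, limma), and for time in solution 7283 were called. Their median rose from 2.18 at 6 h to 2.49 at 12 h and 2.71 at 24 h (means of 4 arrays, SD 0.04, 0.10 and 0.17). The median of the background probes was 1.63, 1.81 and 1.92 at the same times. Over the 12 arrays both medians had a Pearson r of 0.936 (permutation p = 2e-05, 100000 permutations) and a Spearman rho of 0.937 (permutation p = 5e-05). The value of r was 0.93 without the 2 arrays farthest from the median background. The permutations exchanged all 12 arrays freely, while both medians rose with time. These p-values therefore do not measure a link apart from time. Array background may underlie part of the rise of these signals. The Bradyrhizobium median also rose by more than the background median, and the cause of this excess was not tested.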
